A study of Mus musculus with 4 samples.

How the data were processed

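Total RNA from eye tissue of embryos was extracted with Trizol and made into Illumina libraries, per the labels' protocols. There were 4 libraries, 2 from wild-type and 2 from Anp32b-null embryos, grouped and numbered by the labels. The authors deposited a table per library with FPKM values, fragments per kilobase of transcript relative to all fragments of the library, per the file headers. The same tables hold TPM values, per the file headers, which the authors' files give as the FPKM values rescaled to the same sum in each library. The submitters' processing notes name HISAT2, TopHat, Cufflinks and DESeq, without versions or roles, and the builds GRCm38 and GRCh38. Which tool made the values, the annotation release, any filter and the use of strand are not given in the sources used here. Since FPKM divides by the total of all fragments, a fall in very abundant transcripts raises the values of all others, and values of near-identical genes depend on how shared reads were divided.

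Each table listed the same 18702 genes by Entrez number and symbol. Of the symbols, 26 were shown as dates and were restored from the Entrez numbers, and 18647 of the numbers (99.7%) were in the RefSeq gene table of GRCm38. Positions come from the GENCODE annotation of GRCm38.

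The tables hold no read counts, but low FPKM values of genes with a known transcript length lie on steps worth 1 fragment. The spacing over 301 to 309 values per library put the depth between 17820000 and 18060000 fragments. At that depth 64.3% and 64.4% of these values in the wild-type libraries, and 71.1% and 67.9% in the knockout libraries, were within 0.15 of a whole number of fragments, where chance gives 30.0%. Too few were whole for counts to be recovered, so no count test was run, and the depths are estimates. Replicates were compared with counting noise at that depth. Over 1414 single-transcript genes of the wild type and 1455 of the knockout, chi-square per gene was 1.97 and 1.89, and the most abundant genes varied by 2.08% and 1.47% beyond counting noise. The libraries of a group thus differed slightly more than sampling noise and were kept as 2 replicates.

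The test fixed before the data were examined was a count test, with limma-trend as the stated replacement for tables of FPKM, and that replacement is the main test. Values were taken as log2(FPKM + 1), genes with a mean of at least 1 FPKM were kept, and the knockout was compared with the wild type in limma 3.58.1 (R 4.3.3) with a variance trend, genotype as the only term, and a two-sided Benjamini-Hochberg adjusted p under 0.05. The fit had 2 residual and 4.89 prior degrees of freedom. On simulated data for this comparison with the same 13887 genes, 200 of them changed, the fit recovered 85.5% of changes of 0.3 on the log2 scale with 10 false calls, 98.0% of changes of 0.5 with 5, and 100% of changes of 1 with 8. The simulated variance of each gene lay exactly on a trend with expression, unlike that of real genes. Far fewer genes were changed than the 7586 called in the data. These rates therefore check the code and do not carry over to the data.

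Before the data were examined, 28 gene lists for the lens, retina, tissue around the eye, cell cycle, stress and sex-linked genes were fixed from textbook knowledge. Camera, with a preset correlation between genes of 0.01, compared 26 lists of at least 3 measured members with all other genes, and 22 were called, 10 upward and 12 downward. With the correlation estimated from the data, which leaves 2 residual degrees of freedom, camera called 0 lists, the lowest adjusted p was 0.111, and 7 lists had an unadjusted p under 0.05. Fry, which tests whether members move on balance in 1 direction, called 25. Y-linked genes stayed outside these tests. The mitochondrially encoded genes and Xist, on the fixed lists, were not analysed here.

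The genes named in the text were also set by a rule fixed before the data were examined. They were Anp32b and Pax6, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 FPKM and both knockout values beyond both wild-type values, without predicted or sex-linked genes, and the members with the lowest p of each list, up to 4 for the main lists and up to 2 for the others. Some genes that the rule selects are not reported here. List members named beyond this rule were chosen after their values were seen. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of at least 5 FPKM in at least 2 libraries, the replicate number as a block, library scaling without crystallin and erythroid genes, a log2 fold change of at least 1, camera with an estimated correlation, fry, and the omission of each library. Use of the TPM values, over genes with a mean of at least 1 TPM and over the genes tested with FPKM, median-of-ratios scaling and removal of trends with GC content and transcript length were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.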

Results

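Eye tissue from mouse embryos of the C57BL/6 strain was profiled by RNA sequencing of total RNA. The 4 libraries fell into 2 groups, with 2 libraries from wild-type embryos and 2 from embryos labelled as homozygous for a null allele of Anp32b, a gene for an acidic nuclear phosphoprotein that binds histones. The comparison addressed how loss of ANP32B bears on Pax6 and on development of the eye. Each library listed 18702 genes with FPKM values (fragments per kilobase of transcript, relative to all fragments of the library), and low values in the files placed the depth at about 17960000 and 17820000 fragments in wild-type replicates 1 and 2, and at about 17960000 and 18060000 in knockout replicates 1 and 2. The embryonic stage, the sex and the number of embryos behind a library were not given in the sources used here. Nothing says that the libraries of a group came from separate embryos, so the p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels, and errors on FPKM means are SDs with n = 2.

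Anp32b (Entrez 67628, GRCm38 chromosome 4, positions 46450902 to 46472657, plus strand, protein coding), the targeted gene, was lower in both knockout libraries. It stood at 163.18 and 179.12 FPKM in the wild-type libraries and at 94.53 and 92.67 FPKM in the knockout libraries, so that the knockout mean was 54.7% of the wild-type mean. The log2 fold change was −0.86 (SE 0.05, limma adjusted p = 1.11e-05). A value for the whole gene does not show which exons the remaining reads came from, and the deleted part is not described in the sources used here. A processed pseudogene, Anp32b-ps1, carries identical stretches of the transcript, so a small part of the reads could be shared. Among the other members of the ANP32 list, which also holds the histone chaperone gene Set, Anp32e fell from 140.4 ± 8.51 to 110.8 ± 2.43 FPKM (log2 fold change −0.34, adjusted p = 0.000712). Anp32a (146.4 ± 6.25 and 144.7 ± 0.91 FPKM, adjusted p = 0.722) and Set (adjusted p = 0.225) were not past the threshold, but both were called lower with libraries scaled without crystallin and erythroid genes, Set also with median-of-ratios scaling, and Anp32a was called higher with TPM. The list had 2 of 4 members lower, over all genes and adjusted over the list alone. Its camera adjusted p was 0.0307, and adjusted p = 0.399 with an estimated correlation. The call was also lost with TPM, with GC and length trends removed, without wild-type replicate 2 (adjusted p = 0.0572) and without knockout replicate 1 (adjusted p = 0.0504), within a range of 0.0060 to 0.399 over all alternatives.

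Pax6 (Entrez 18508, GRCm38 chromosome 2, positions 105668900 to 105697364, plus strand), the paired-box and homeobox regulator of eye formation named in the title of the series, fell to 68.5% of its wild-type mean. Its values were 160.94 and 158.43 FPKM in the wild-type libraries and 107.76 and 110.97 FPKM in the knockout libraries, a log2 fold change of −0.54 (SE 0.03, adjusted p = 1.28e-05). The antisense gene Pax6os1 overlaps its 5′ end on the minus strand, and whether reads were assigned by strand is not given in the sources used here. Crystallins (median −3.51) were lower and skeletal muscle genes (median 1.04) higher in the libraries in which Pax6 was lower.

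Among changed genes with a mean of at least 5 FPKM, genes of the lens lists gave the 8 largest falls, and the largest rises were those of Ibsp and Spp1, known from mineralised bone matrix. Of 13887 genes tested, 7586 changed in the knockout, 4654 higher and 2932 lower, so 61.4% of the changed genes were higher. Changes of at least 1 on the log2 scale were limited to 326 genes, 211 higher and 115 lower. The 8 largest falls at that level were Crygf, Crygb, Crybb2, Crygd, Cryga, Bfsp1, Bfsp2 and Cryge, with log2 fold changes from −4.01 to −3.63. The 8 largest rises at the same level were Ibsp, Spp1, Alpl, Vax1, Krt17, Bmpr1b, Ccl21a and Clec11a. Ibsp, the bone sialoprotein gene, went from 0.95 ± 0.25 to 49.2 ± 0.09 FPKM (log2 fold change 4.69, adjusted p = 1.22e-07). Spp1, which encodes osteopontin, went from 12.3 ± 0.59 to 86.7 ± 1.57 FPKM (2.72), and Alpl, the tissue-nonspecific alkaline phosphatase, from 3.42 ± 0.08 to 15.7 ± 0.21 FPKM (1.92). Vax1, a homeobox gene of the optic stalk, rose from 2.33 ± 0.05 to 10.6 ± 0.55 FPKM (1.80) and the keratin Krt17 from 13.2 ± 0.13 to 44.8 ± 0.76 FPKM (1.69). The rises of the BMP receptor gene Bmpr1b (1.69), the chemokine gene Ccl21a (1.65) and the growth factor gene Clec11a (1.59) were of similar size, with Ccl21a uncertain because near-identical copies exist. In 10820 genes, 77.9% of those tested, both knockout values lay beyond both wild-type values. Chance gives 33.3% only if the 4 libraries are independent samples, which the sources used here do not state. If the libraries of a group share a source, this separation says little about genotype. How the libraries are scaled moved the split between higher and lower genes. It was 7182 higher and 1721 lower with the deposited TPM values (80.7% higher), tested over the 15037 genes with a mean of at least 1 TPM. Over the same 13887 genes as with FPKM it was 6926 higher and 1667 lower (80.6% higher), and the median log2 fold change of these genes was 0.16 with TPM and 0.04 with FPKM. With libraries scaled without the crystallin and erythroid genes it was 3533 higher and 4330 lower (44.9% higher).

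**Figure D1:**
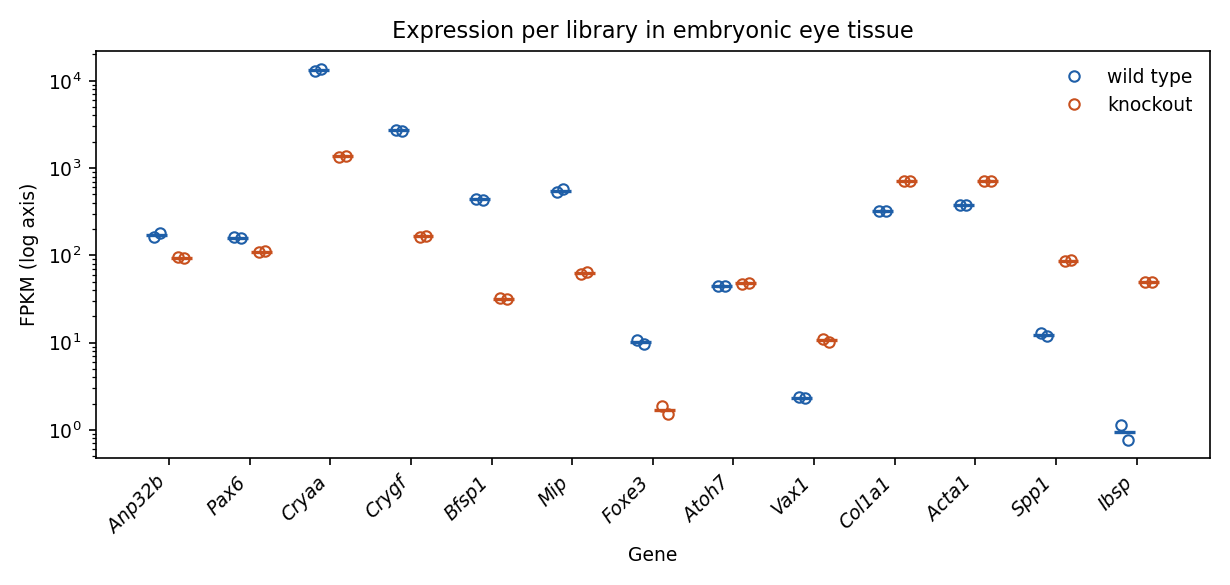
FPKM on a log axis for 13 genes in each library, with wild type in blue and knockout in orange, circles for the 2 libraries of a group and a bar for their mean. Crygf stood at 2693 FPKM in the wild type and 166 FPKM in the knockout, Anp32b and Pax6 at 54.7% and 68.5% of their wild-type means, and Ibsp rose to 49.2 FPKM.

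Lens genes fell together. All 16 crystallins, the structural proteins of the lens, were lower in the knockout over all genes and adjusted over the list alone, with a median log2 fold change of −3.51. The 6 gamma crystallins from Cryga to Crygf were between 11.9-fold and 16.2-fold lower, the 6 beta crystallins between 8.70-fold and 16.3-fold, and the alpha crystallins Cryaa and Cryab 9.81-fold and 5.49-fold. Crygf went from 2693 ± 58.2 to 166.2 ± 3.30 FPKM (adjusted p = 2.71e-09), Crygb from 4646 ± 98.8 to 296.8 ± 2.98 FPKM, Cryba4 from 1861 ± 10.2 to 159.7 ± 0.02 FPKM, and Crygc from 2444 ± 24.1 to 205.1 ± 1.63 FPKM. The share of the crystallins in the FPKM sum of a library was 15.0% and 14.9% in the wild type and 1.43% in each knockout library. The gamma crystallins are close paralogs, so reads may have been divided among them, and the value of any of these copies is uncertain. Among 18 lens fibre genes and lens regulators all 18 were lower, again by both adjustments, with a median of −2.47. The beaded filament genes Bfsp1 and Bfsp2 were 13.7-fold and 13.1-fold lower and the fibre membrane gene Lim2 11.6-fold. Of the regulators, Foxe3, a forkhead factor of the lens epithelium, fell from 10.2 ± 0.71 to 1.70 ± 0.23 FPKM. Camera gave adjusted p = 5.88e-22 for the crystallins and 6.05e-19 for the lens fibre list, and adjusted p = 0.111 for both with an estimated correlation. In the same libraries skeletal muscle genes were higher by a median of 1.04.

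Transcription factors of the eye field and optic cup went both ways. Of 16 measured members, 9 were lower and 5 higher, by both adjustments, with a median log2 fold change of −0.16. Six6, a homeobox gene of the optic cup, fell from 32.2 ± 0.45 to 21.1 ± 0.80 FPKM (−0.59). The higher members were Vax1, Eya2 (0.76), Vax2 (0.53), Eya1 (0.29) and Otx2 (0.09). The rises of Eya1 and Otx2 were not past the threshold with libraries scaled without crystallin and erythroid genes or with median-of-ratios scaling, and the small fall of Rax (−0.11) changed sign with TPM. Camera gave adjusted p = 0.0307 and, with an estimated correlation, adjusted p = 0.224, and the call was lost with median-of-ratios scaling and with libraries scaled without crystallin and erythroid genes. Pax2 and Tbx5 were below the level tested.

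Among 17 genes described as direct or indirect targets of PAX6, 14 were lower and 3 higher by both adjustments, and the median was −0.62. Crygf, Crybb1 (6282 ± 23.1 to 556.7 ± 12.7 FPKM), Cryab (1135 ± 10.6 to 206.8 ± 3.49 FPKM) and Cryaa (13324 ± 308 to 1358 ± 10.7 FPKM) had the lowest p-values. Of the 17, 7 also belong to the lens lists. Among the 10 outside them, 7 were lower, such as Optc (−1.19), and 3 were higher, while with TPM Mab21l1 and Neurod1 were no longer past the threshold on the lower side. These were Sfrp2 (1.13), a secreted Wnt modulator, and the proneural genes Neurog2 (0.19) and Atoh7 (0.10), of which Atoh7 was not past the threshold under median-of-ratios scaling and neither proneural gene was with libraries scaled without crystallin and erythroid genes. In the camera test the list had adjusted p = 5.05e-08, and adjusted p = 0.111 with an estimated correlation. Skeletal muscle genes (median 1.04) and mesenchyme genes (median 0.95) were higher in the same libraries.

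Genes of retinal progenitors and of retinal ganglion cells were mostly lower, by less than the lens genes. Of 15 progenitor genes 11 were lower and 1, Sfrp2, was higher, by both adjustments, with a median of −0.47. The cyclin gene Ccnd1 fell from 707.1 ± 5.55 to 376.5 ± 3.13 FPKM (−0.91, adjusted p = 1.6e-06) and Fgf15 from 169.2 ± 3.38 to 108.5 ± 0.36 FPKM (−0.64). Sfrp2 rose from 34.1 ± 1.28 to 76.1 ± 0.39 FPKM. Of 13 ganglion cell genes 12 were lower and 1, Atoh7, was higher with FPKM but not under either rescaling of it, by both adjustments, with a median of −0.55. The neurofilament gene Nefl fell from 54.6 ± 0.52 to 26.4 ± 0.59 FPKM (−1.02), Sncg by a similar amount (−1.03), Thy1 by less (−0.66) and Stmn2 by less again (−0.41). In the camera test adjusted p was 3.37e-06 for progenitors and 5.24e-07 for ganglion cells. With an estimated correlation these were adjusted p = 0.162 and adjusted p = 0.165. Skeletal muscle genes (median 1.04) and mesenchyme genes (median 0.95) were higher in the libraries in which these genes were lower.

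Lists of other retinal cell types had medians nearer 0, with members that moved both ways in most of them. Of 12 amacrine and horizontal cell genes 7 were lower, led by Calb2 (61.8 ± 0.18 to 23.9 ± 0.08 FPKM, −1.33) and the GABA-synthesis gene Gad1 (−0.53). Gad2 (0.36) and Slc6a9 (0.14) were higher, Slc6a9 not under either rescaling of FPKM, and adjusted over the list alone a further member passed, to make 3 higher. With TPM 4 were lower and 3 higher, as Ptf1a, Tfap2b and Onecut2 were not past the threshold and Lhx1 was called higher. Of 19 photoreceptor genes 9 were lower and 6 higher by both adjustments. Under either rescaling of FPKM 10 were lower and 4 higher, as Otx2 and Rxrg were not past the threshold and Thrb was called lower. The rod regulator Nr2e3 fell from 25.1 ± 1.20 to 11.7 ± 0.06 FPKM (−1.05), and Sag (−1.11) and Pde6b (−1.17), of rod phototransduction, fell as well. Opn1sw, the short-wave cone opsin, rose from 27.9 ± 0.30 to 48.4 ± 1.64 FPKM (0.77). Of 4 bipolar cell genes 3 were lower by both adjustments, namely Cabp5 (−0.80), Trpm1 (−0.51) and Prkca (−0.22), the last not past the threshold with TPM. Of 14 pigment cell and retinal pigment epithelium genes 8 were lower and 1 higher, by both adjustments, and 6 lower and 2 higher with TPM. The melanosome genes Pmel (−0.39) and Dct (−0.45) and the retinal opsin-like gene Rgr (−0.82) fell, whereas the thyroxine carrier gene Ttr rose from 30.1 ± 0.09 to 59.0 ± 0.26 FPKM (0.95). Camera gave adjusted p = 0.0142 for amacrine and horizontal cells, 0.0376 for bipolar cells and 0.00184 for pigment cells, and did not call photoreceptors (adjusted p = 0.0792). With an estimated correlation the called lists had adjusted p = 0.207, adjusted p = 0.233 and adjusted p = 0.165. Without wild-type replicate 1 the bipolar call was lost (median −0.39), as it was under both FPKM rescalings and without a filter, where the median turned to 0.03. Over all alternatives the adjusted p of the bipolar list ran from 0.0013 by fry to 0.264 by camera. Without knockout replicate 2 the photoreceptor list was called (median −0.12), as it was with TPM, without a filter and by fry. The adjusted p of the photoreceptor list ran from 0.0042 by fry to 0.350 by camera. Muscle genes (median 1.04) and mesenchyme genes (median 0.95) were higher in the same libraries.

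**Figure D2:**
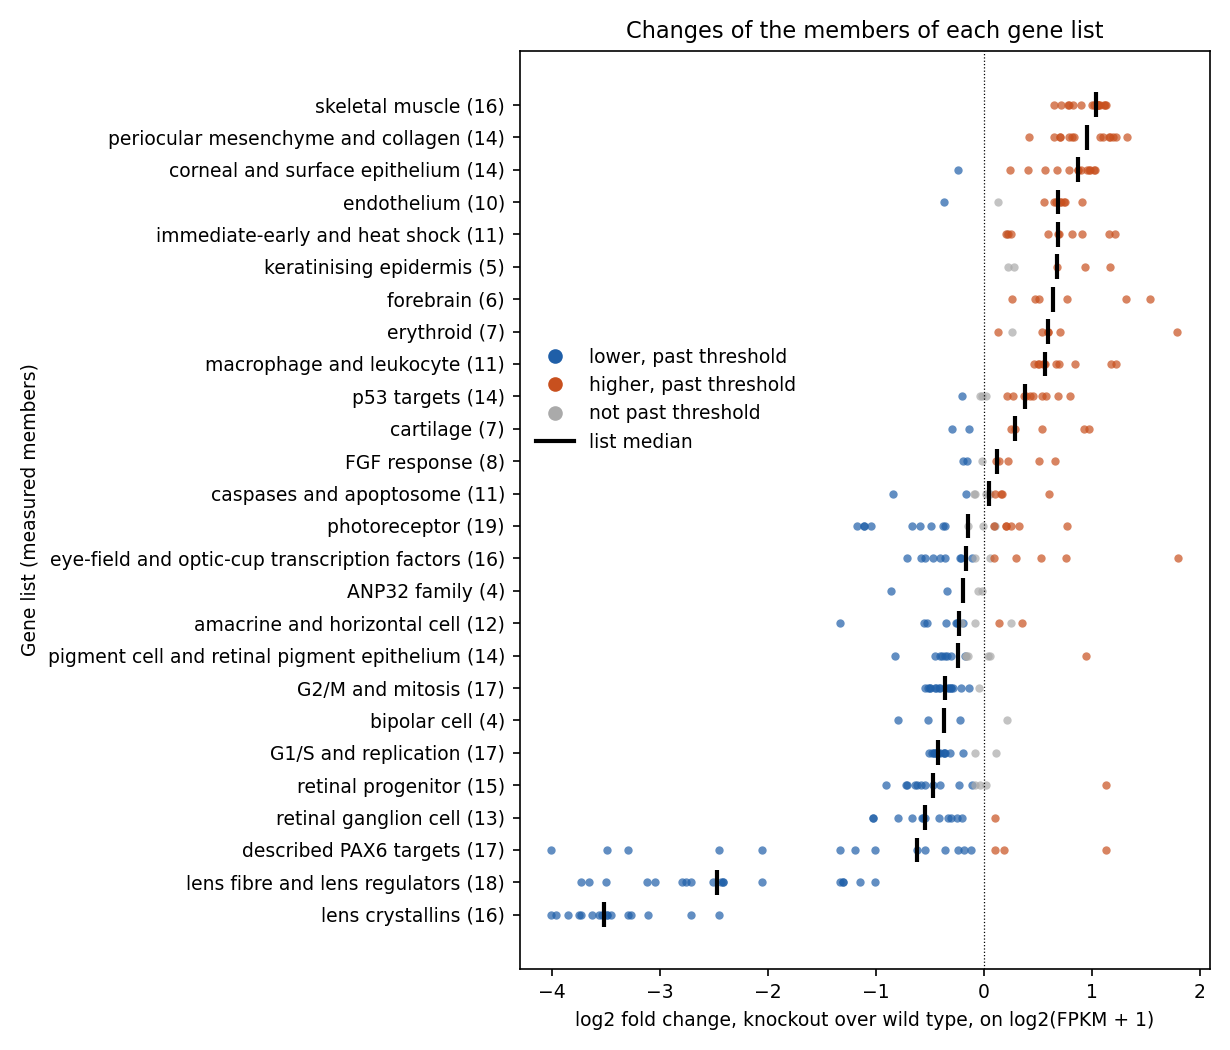
Log2 fold change of each measured member of 26 gene lists (x axis, knockout over wild type on log2(FPKM + 1)), with lists on the y axis in order of their median, blue points for genes lower and orange for genes higher past the threshold, grey for the rest and a black bar for the list median. Lens crystallins sit lowest with a median of −3.51 and skeletal muscle highest with a median of 1.04.

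Genes of muscle, connective tissue and surface epithelium rose together. All 16 skeletal muscle genes were higher, with a median of 1.04, among them the perinatal myosin Myh8 (87.5 ± 1.64 to 191.0 ± 0.11 FPKM) and the creatine kinase Ckm (118.7 ± 1.48 to 248.7 ± 3.88 FPKM). All 14 genes of periocular mesenchyme and collagen were higher, with a median of 0.95, such as Lum, a stromal proteoglycan (77.0 ± 0.11 to 174.7 ± 2.54 FPKM), and Col1a1 (320.1 ± 2.27 to 714.1 ± 1.68 FPKM). Of 14 genes of corneal and surface epithelium 13 were higher, with a median of 0.87, including Krt15 (258.1 ± 9.55 to 525.4 ± 3.16 FPKM) and the desmosomal gene Perp (0.90). The exception was Krt12, the keratin of corneal epithelium, which fell (−0.24). These counts were the same adjusted over the list alone. Of 5 genes of keratinising epidermis 3 were higher over all genes, Krtdap (1.17), Krt1 (0.94) and Dsg1a (0.68), and 4 adjusted over the list alone. Of 7 cartilage genes 5 were higher by both adjustments, Col11a1 (0.97), Acan (0.93), Hapln1 (0.54), Sox9 (0.29) and Col9a2 (0.25), and 2 were lower, Col2a1 (−0.29) and Col9a1 (−0.14), the latter not past the threshold with TPM. By camera, adjusted p was 1.36e-09 for muscle, 1.87e-08 for mesenchyme, 3.37e-06 for surface epithelium and 0.0174 for epidermis, and cartilage was not called (adjusted p = 0.206). With an estimated correlation the called lists had adjusted p = 0.162, adjusted p = 0.111, adjusted p = 0.133 and adjusted p = 0.231. The epidermis call was also lost without a filter on low values, where all 11 fixed genes entered and the median was 0.06, and with TPM over the genes with a mean of at least 1 TPM. Fry, unlike camera, called the cartilage list (adjusted p = 0.0035).

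Genes of blood, vessels, leukocytes and forebrain were also higher. Of 7 erythroid genes 6 were higher over all genes and 7 adjusted over the list alone. The adult globin gene Hbb-bt rose from 634.7 ± 16.4 to 1036 ± 38.3 FPKM (0.71), and Hbb-y, an embryonic globin gene, from 0.46 ± 0.13 to 4.04 ± 0.13 FPKM (1.79). Hbb-bt and Hbb-bs, like Hba-a1 and Hba-a2, are near-identical copies whose separate values are uncertain. Of 10 endothelial genes 8 were higher, 9 adjusted over the list alone, with Pecam1 at 0.91 and Cdh5 at 0.71, and 1, the VEGF receptor gene Kdr, was lower (−0.37). All 11 macrophage and leukocyte genes were higher by both adjustments, with a median of 0.57, and Tyrobp (1.22) and Lyz2 (1.18) had the lowest p-values. All 6 measured forebrain genes were higher by both adjustments, but 3 of them, Dlx5, Emx2 and Lhx6, were below 1 FPKM in the wild type and entered the test through their knockout values. With libraries scaled without crystallin and erythroid genes 5 were higher, without Dlx2. Dlx5, also a gene of bone-forming cells, rose from 0.14 ± 0.08 to 2.32 ± 0.04 FPKM (1.54). Camera gave adjusted p = 0.00184 for the erythroid list, 0.00238 for endothelium, 0.000165 for leukocytes and 0.0098 for forebrain. With an estimated correlation these were adjusted p = 0.259, adjusted p = 0.165, adjusted p = 0.165 and adjusted p = 0.268.

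Cell-cycle genes fell by about 0.4 on the log2 scale. Of 17 genes of G1/S and DNA replication 15 were lower and none higher, although Ccne1 was called higher with TPM, with a median of −0.42. The replicative helicase genes Mcm7 (88.2 ± 0.57 to 63.1 ± 0.74 FPKM), Mcm3 (−0.47) and Mcm6 (−0.43) and the maintenance methylation cofactor Uhrf1 (−0.41) had the lowest p-values. Of 17 genes of G2/M and mitosis 16 were lower and none higher, with a median of −0.36, led by Top2a (120.1 ± 1.78 to 82.0 ± 0.76 FPKM), Mki67 (−0.52), Ccna2 (−0.50) and Ccnb2 (−0.50). Both counts were the same adjusted over the list alone. For the cell-cycle lists camera gave adjusted p = 4.47e-08 and 2.48e-09, and adjusted p = 0.111 for both lists with an estimated correlation. The same libraries had higher values of muscle genes (median 1.04).

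Of 14 p53 target genes 10 were higher and 1, Aen, was lower (−0.21), by both adjustments, with a median of 0.38. Phlda3 (0.80), the cell-cycle inhibitor Cdkn1a (29.9 ± 0.66 to 48.6 ± 0.97 FPKM, 0.68), Plk2 (0.57) and Ccng1 (0.39) had the lowest p-values, while Mdm2 (0.02), Bax (−0.04) and Bbc3 (−0.02) were not past the threshold. Aen was not past it and Mdm2 was called higher with TPM, while Bax was called lower with libraries scaled without crystallin and erythroid genes, and Zmat3 (0.22) was not past it under either rescaling of FPKM. In the camera test the p53 list had adjusted p = 0.0197, and adjusted p = 0.328 with an estimated correlation. Muscle (median 1.04), mesenchyme (0.95), surface epithelium (0.87) and immediate-early and heat shock genes (0.68) were higher in the same libraries. Of 11 caspase and apoptosome genes 4 were higher, Casp8 (0.60), Bak1 (0.17), Apaf1 (0.16) and Cycs (0.11), and 2 were lower, among them Diablo (−0.16), by both adjustments. Bak1, Apaf1 and Cycs were not past the threshold under either rescaling of FPKM, nor Diablo with TPM. The list was not called (adjusted p = 0.843). Its median was above 0 and its mean below 0, and its median fell below 0 with libraries scaled without crystallin and erythroid genes. Of 8 FGF response genes 5 were higher, Spry1 (0.66), Spry4 (0.51), Etv1 (0.22), Spred1 (0.14) and Dusp6 (0.11), and 2 were lower, Etv4 (−0.20) and Etv5 (−0.15), by both adjustments, and camera did not call the list (adjusted p = 0.441). Spred1 and Dusp6 were not past the threshold under either rescaling of FPKM, nor Etv1 with libraries scaled without crystallin and erythroid genes, nor Etv4 and Etv5 with TPM. Fry, unlike camera, called the FGF response list (adjusted p = 0.0076). Of 11 immediate-early and heat shock genes, which respond to handling of tissue as well as to signals, 10 were higher over all genes and 11 adjusted over the list alone. Fos rose from 6.92 ± 0.25 to 16.7 ± 0.09 FPKM (1.16) and Jun from 27.9 ± 0.93 to 42.6 ± 1.41 FPKM (0.60). With libraries scaled without crystallin and erythroid genes 8 were higher, without Ier2 and Dusp1, and with median-of-ratios scaling 9, without Dusp1. Camera gave adjusted p = 0.000224, and adjusted p = 0.218 with an estimated correlation. All 4 Y-linked genes measured were lower by both adjustments, with Eif2s3y at 12.7 ± 0.41 and 8.63 ± 0.48 FPKM and Ddx3y at 5.15 ± 0.23 and 3.51 ± 0.18 FPKM in wild type and knockout. As the sex of the embryos was not given, whether the share of males differed between the groups is not known.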

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

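The use of TPM values, over their own or the FPKM genes, median-of-ratios scaling and removal of GC and length trends were chosen after seeing the data. Anp32b and Pax6 kept their direction and their side of the threshold under each alternative fitted gene by gene, and so did the other genes that the rule selects, in the 1073 comparisons that could be made. Genes below a stricter filter had none, and the fold threshold, which Anp32b and Pax6 do not reach, was applied to counts of genes. Anp32b ranged from −0.94 to −0.75 over these alternatives and Pax6 from −0.62 to −0.42. The 7586 changed genes became 326 (211 higher, 115 lower) with a log2 fold change of at least 1, and the 4654 higher and 2932 lower genes became 7182 and 1721 with TPM (1667 lower over the genes tested with FPKM), whose construction raises all knockout values relative to FPKM. Calls ranged from 5415 to 6225 without any single library, with 69.9% to 78.9% of the original calls shared, and these fits assume that the lone library of a group varies like the other group. Camera called 20 to 23 lists under the remaining settings and 0 with an estimated correlation, while fry called 25. In 35 comparisons a list lost its call, 22 of them with the estimated correlation, and in 7 a list gained a call. Among list members called with FPKM, small changes such as those of Eya1 and Alas2 lost their calls under another scaling, and Rax changed sign with TPM. Apart from the estimated correlation, the lost calls were those of the ANP32, eye-field, bipolar cell and epidermis lists. With the replicate block, 7828 genes were called, 4781 higher and 3047 lower. Libraries with the same number did not deviate together (correlation 0.04). With 2 libraries per group this is a single value, and replicates differed only slightly beyond sampling noise. It therefore does not settle whether the numbers pair the samples. The tests that need counts, edgeR with other size factors, DESeq2 and limma-voom, were not run because the files hold no counts, and the count filters were run as FPKM filters. At the estimated depth the spread of low genes is set mainly by counting, with an SD of 0.25 on the log2 scale per wild-type library for genes with 40 to 200 fragments over both libraries.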

Other observations

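Of the tests below, those of crystallin loss, of GC and length trends, of lens share, of tissue around the eyeball, of blood, of Hbb-bs reads and of shared Anp32a or Anp32e sequence were chosen after the result was seen. The lists of bone formation, of retinoic acid metabolism and of genes that fall with embryonic age were written after the largest changes had been seen and before their other members were looked at.

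Further genes of bone formation were higher beside Ibsp, Spp1 and Alpl. All 7 measured members of a list of bone genes rose, over all genes and adjusted over the list alone, with a median log2 fold change of 0.90. Sp7, Dmp1, Ifitm5 and Omd were below 1 FPKM in the wild type and entered the test through their knockout values, so the filter helps to set that count. Dmp1, a matrix gene of osteocytes, rose from 0.08 ± 0.03 to 6.68 ± 0.16 FPKM (2.83, adjusted p = 1.17e-06). Sp7, the transcription factor osterix, rose from 0.42 ± 0.06 to 4.88 ± 0.29 FPKM (2.05) and Ifitm5 from 0.71 in both wild-type libraries to 4.38 ± 0.01 FPKM (1.65), while Runx2 (0.64) rose by less.

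Enzymes of retinoic acid metabolism moved apart. Of 12 genes 5 were higher, 4 lower and 3 not past the threshold, and 6 were higher adjusted over the list alone. The degrading enzyme Cyp26a1 fell from 21.1 ± 0.37 to 4.12 ± 0.24 FPKM (−2.11, adjusted p = 6.98e-07) and Cyp26c1 from 2.78 ± 0.40 to 0.23 ± 0.09 FPKM (−1.62), whereas Cyp26b1, also a degrading enzyme, rose from 2.60 ± 0.15 to 5.42 ± 0.04 FPKM (0.83, adjusted p = 7.83e-05). Among the synthesising enzymes Aldh1a1 fell from 117.4 ± 1.63 to 33.3 ± 0.30 FPKM (−1.79), Aldh1a2 rose from 8.30 ± 0.47 to 17.5 ± 0.33 FPKM (0.99), and Aldh1a3 stood at 22.6 ± 0.42 and 24.3 ± 0.58 FPKM (adjusted p = 0.0603). Aldh1a1 and Cyp26a1 had been seen among the largest falls before the list was written.

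Lens and retinal lists were lower while mesenchyme and muscle lists were higher. Loss of crystallin reads can raise other log2 values by at most 0.21, and the mesenchyme median stayed at 0.88 with libraries scaled without crystallin and erythroid genes. A smaller lens alone would raise all other tissues alike, yet the mesenchyme and retinal progenitor medians lay 1.42 apart, beyond the larger interquartile range of 0.53. They lay 1.41 apart after GC and length trends were removed, whereas the 7630 genes then called do not bear on the lists. A larger share of tissue from around the eyeball would lower lens and retinal genes alike. The medians were −3.51 for crystallins (quartiles −3.74 to −3.29), −2.47 for lens fibre genes (−2.98 to −1.51) and −0.47 for retinal progenitors (−0.63 to −0.09). This gap argues against such tissue as the only cause of the pattern. As a part of the cause it stays open, as does a smaller lens and retina through the genotype, which was not tested separately. The medians above 0 in 8 of 8 lists assigned to such tissue (84 genes, 82 of them at 1 FPKM or more in the wild type and 1, Krt12, on a further list) largely restate the pattern. These lists include genes of cornea, vessels, blood and leukocytes, which are not limited to tissue around the eyeball.

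Anp32b kept 54.7% of its wild-type level in libraries labelled as null. No 50-base window of its transcript occurs in Anp32a or Anp32e (0% of 1667 windows), which argues against their reads as the source. The pseudogene Anp32b-ps1 holds 12.1% of the windows, between the bounds set for excluding and for keeping shared reads, so this stays open, as does a transcript that persists around a deleted part, which was not analysed here. Whether every embryo behind the knockout libraries carried the labelled genotype was not tested. A fall through tissue makeup alone is not excluded by the test set for it. That outcome rests on Ccnd1, which fell by 0.91 on the log2 scale, for reasons that were not tested. The next lowest of the 49 progenitor and cell-cycle genes was Nr2e1 at −0.72, and the list medians were −0.47, −0.42 and −0.36. Of 1323 genes with means of 50 to 500 FPKM outside the lens lists, only 13 (0.98%), Anp32b itself among them, fell that far. These genes also include muscle and mesenchyme genes that rose, so the share says little about genes of the retina. Neither comparison held genes of the lens lists. All 18 lens fibre genes and lens regulators fell further than Anp32b, the least of them Prox1 (−1.01). The comparisons therefore cannot show how far tissue makeup alone would lower a gene that is also expressed in lens.

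The embryonic globin Hbb-y rose further than the adult globins, and the ratio of Hbb-y to Hbb-bs rose by 2.56 on the log2 scale (SD 0.24 between replicates). That ratio restates the pattern and rests on a gene at 0.46 FPKM in the wild type and on Hbb-bs, which has a near-identical copy, so more blood in the tissue and reads of Hbb-bs assigned to Hbb-y both stay open. An earlier stage of the knockout embryos may contribute and cannot be told apart from other effects of genotype, since a list of genes that fall with embryonic age had a median of 0.18, with Igf2bp1, Igf2bp2 and Igf2bp3 higher, Hmga1 and Hmga2 lower, and Lin28b not past the threshold. The labels give no stage.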
